A study of Drosophila melanogaster with 7 samples.

How the data were processed

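RNA was measured in dissected midguts of Drosophila melanogaster, the part of the fly gut that digests and absorbs food. Per the labels, virgin females of the strain labelled sg-Gal4,UAS-GFP were housed at 10%, 20% or 40% oxygen. Gut RNA was taken at day 53 with a Qiagen RNeasy Plus Mini kit and made into strand-specific mRNA libraries for DNBSEQ sequencing. The 7 libraries comprise 3 at 10% oxygen, 3 at 20% and 1 at 40%. Replicates 1 and 2 at 10% and 20% oxygen carry batch 1 in the labels. Replicate 3 of both groups and the library at 40% carry batch 2. The labels do not say that replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

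The authors deposited 1 transcript quantification table per library, per the file headers with expected counts (estimated numbers of reads per transcript, which need not be whole), TPM (transcripts per M, or mega, transcripts) and effective transcript length, together with a table that pairs transcripts with genes. STAR 2.7.11b and Salmon 1.10.3 are named in the submitters' processing notes; the settings and the genome build are not given in the sources used here. All 41539 transcripts in the files have the length that the Ensembl annotation of assembly BDGP6.54 gives them, so coordinates below are from that annotation. The gene table resolves to 24204 features, of which 17834 have a FlyBase gene number the others including transposon insertions, and all 24204 are in the annotation.

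The deposited expected counts were summed per gene and rounded to whole numbers. Library totals ranged from 19.22 to 22.22 M counts (M for mega), so 3 counts, taken as the detection floor, correspond to 0.135 to 0.156 CPM (counts per M counts). Shares of a library's counts have exact Clopper-Pearson 95% intervals; the widest for a mitochondrial share spans 0.044 percentage points, and intervals and floors cover counting error only. No pair of libraries agreed within sampling noise: over features with at least 20 counts in a pair, chi-square per degree of freedom was 35.1 or more.

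The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM scaling, the filterByExpr filter and batch as a covariate, with Benjamini-Hochberg adjusted p below 0.05 as the threshold for a call. The comparison of 10% with 20% oxygen used the 6 libraries of those groups and 9278 features passed the filter. The comparisons of 40% with 20% and with 10% used all 7 libraries and 10068 features; the single 40% library has no replicate, and its spread was assumed to be that of the other libraries. Standard errors (SE) of log2 fold changes are those implied by the test statistic. Levels per library are TMM-scaled CPM from the fit of all 7 libraries. TMM factors ranged from 0.457 in the 40% library to 1.63 in replicate 2 at 20%. On that scale 3 counts are a different level in each library, highest in the 40% library. On data simulated from the real means, library sizes and dispersions, with 9123 genes run for 10% against 20%, edgeR recovered 42 of 100 genes changed 2-fold and 93 of 100 changed 4-fold, with 12 unchanged genes among 147 calls. For 40% against 20%, with 9885 genes run, it recovered 1 of 100 genes changed 2-fold and 46 of 100 changed 4-fold, with 1 unchanged gene among 48 calls. DESeq2 in the simulation of 10% against 20% recovered 72 of 100 genes changed 2-fold and 99 of 100 changed 4-fold, with 43 unchanged genes among 214 calls. For 40% against 20% DESeq2 recovered 31 of 100 genes changed 2-fold and 69 of 100 changed 4-fold, with 39 unchanged genes among 139 calls. In all these simulations the changed genes were drawn only from those above a minimum mean count. Recovery of genes with low counts was therefore not measured.

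Same-numbered libraries at 10% and 20% oxygen share a batch in the labels. Their deviations from the group means correlated across genes at 0.384, 0.415 and 0.693 for numbers 1, 2 and 3. Libraries of different number within batch 1 correlated as highly, at 0.383 and 0.476, and with the batch removed numbers 1 and 2 did not pair (r = -0.0361). Batch is therefore in the main tests; fits with the replicate number as a block and with no batch term were alternatives.

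Gene lists, 39 in all, were fixed before the data were examined, each by gene symbols. The pathway lists were hypoxia response, glycolysis, TCA cycle, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, antioxidant enzymes, glutathione S-transferases, cytochrome P450s, UDP-glycosyltransferases, metallothioneins, heat shock proteins, endoplasmic reticulum stress, antimicrobial peptides, the Imd pathway, JAK-STAT, JNK signalling and apoptosis, EGFR, insulin and FOXO, cell cycle, DNA damage repair, ribosomal proteins, proteasome, lipid synthesis, lipid breakdown, serine proteases, carbohydrate-digesting enzymes, V-type proton pumps, peritrophic matrix and septate junctions. Midgut cell types were represented by progenitors, enteroendocrine cells and enterocytes with copper cells. Other cell types a dissection can carry along were represented by muscle, trachea, haemocytes, fat body, ovary, Malpighian tubule with hindgut, and neurons. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, which asks whether a list's genes move on balance 1 way.

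Genes were named by a rule also fixed before the data were examined. For 10% against 20% it took up to 10 called genes each way with an average of at least 2 log2 CPM whose 10% libraries all lay beyond the 20% libraries of their batch. For 40% against 20% it took up to 8 each way whose 40% library lay beyond every 20% library, and for 40% against 10% up to 3. From each list it took up to 3 called members with the smallest p. Where fewer than 5 genes were called in a direction, those with the smallest p filled up to 5. The genes sima, Hph, Ldh, esg, Delta, upd3 and GstD1 were always given. Other members named beside a count for their list, partners of overlapping genes, and genes named in the closing section were chosen after their values were seen.

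The alternatives were DESeq2 size factors, DESeq2's Wald test (1.42.0), limma voom, no filter on low counts, at least 10 counts in 3 libraries, no batch term, offsets for effective length, limma on log2(TPM + 1) of the deposited TPM values for genes with a mean TPM of at least 1, removal of the 20 most abundant genes, and leaving out each replicate in turn. For 10% against 20% a replicate block, all 7 libraries and batch 1 alone were run too. Offsets that remove a smooth trend of each library's log2 CPM on gene length, and removal of genes at 0 counts in one library and at least 50 in another (all-or-none genes), and list tests in batch 1 alone, were chosen after seeing the data.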

Results

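The series asked how the oxygen level under which adult flies live affects the upkeep of the midgut, comparing 10% oxygen (hypoxia) and 40% oxygen (hyperoxia) with 20% oxygen (normoxia) at day 53. Total counts were 21.87, 21.88 and 19.22 M (mega) in replicates 1, 2 and 3 at 10% oxygen. They were 21.52, 22.22 and 19.41 M at 20%, and 19.79 M in the 1 library at 40%.

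The libraries differed most by batch. Transcripts of the mitochondrial genome made up 4.29% and 4.68% of counts in batch 1 at 10% oxygen and 4.10% and 4.52% at 20%, against 61.0% and 64.0% in batch 2 and 71.0% in the 40% library. Most of the excess was the large mitochondrial ribosomal RNA, mt:lrRNA, at 2.5% to 2.93% in batch 1, 42.6% and 43.0% in batch 2 at 10% and 20%, and 48.8% at 40%. Counts outside the mitochondrial genome were 20.64 to 21.22 M in batch 1 and 7.49, 7.0 and 5.73 M in batch 2 at 10%, 20% and 40%. Muscle genes stood 4.14 log2 units higher in batch 2 (median of 16 tested genes), and tracheal genes 2.77 (median of 11). The mean sequenced fragment, from the deposited effective lengths, was 273 to 281 bases in batch 1, 245.3 and 254.7 bases in batch 2 at 10% and 20%, and 230 bases at 40%. The first principal component held 61.3% of the variance and separated the batches. Within batch 1, replicate 2 at 10% oxygen stood apart in transcripts of neighbouring organs: Uro, the urate oxidase of Malpighian tubules, was at 8.22 CPM against 68.0 to 126 in the other batch 1 libraries, and the oocyte gene osk was at 0.142 CPM against 8.72 to 40.5.

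**Figure D1:**
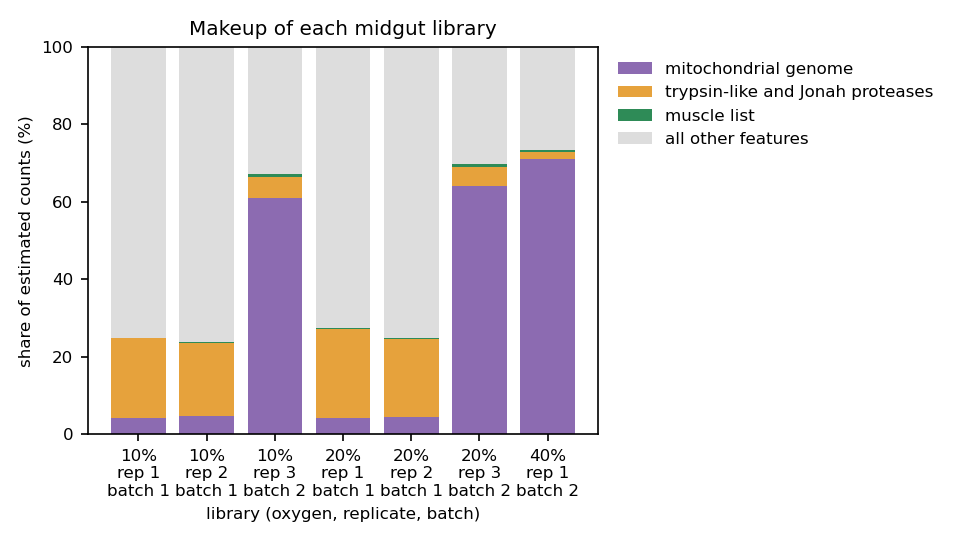
Share of estimated counts (%, vertical axis) taken by the mitochondrial genome, the trypsin-like and Jonah serine protease list, the muscle list and all other features in each of the 7 libraries (horizontal axis). The mitochondrial share is 4.10% to 4.68% in the 4 libraries of batch 1 and 61.0%, 64.0% and 71.0% in batch 2, and the protease share is lowest, 1.85%, in the 40% library.

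At 10% oxygen edgeR called 0 genes against 20%, with 584 at an unadjusted p below 0.05, while limma voom called 1 and DESeq2 124. Of the 39 gene lists 12 passed by camera at the preset correlation. None of the 12 passed with an estimated correlation (adjusted p from 0.446 to 0.718). By fry the TCA cycle and fat body lists passed (adjusted p = 0.0484 for each), and the others of the 12 did not (0.0916 to 0.661). The TCA cycle and nuclear-encoded oxidative phosphorylation lists fell by small amounts: all 19 tested TCA cycle genes had fold changes below 0, with a median log2 fold change of -0.14, and 63 of 68 nuclear-encoded subunits of oxidative phosphorylation did, with a median of -0.15. The cell cycle list fell by more, with 28 of 31 genes below 0 and a median of -0.57, and the ovary list fell with it (median -1.26). On the TPM scale, over genes with a mean TPM of at least 1 and relative to all genes, these medians were -0.23 and -0.90. With the germline level of each library as a covariate, the mean difference of the cell cycle list across the 6 libraries was -0.36 (SE 0.37), against -0.59 (SE 0.29) without it. The carbohydrate-digesting list rose, with 18 of 20 enzymes above 0 and a median of 0.40, which was 0.20 without replicate 3 at 10% or at 20% and 0.21 in batch 1 alone. The list of the peritrophic matrix and mucins rose, with 15 of 22 genes of this chitin and mucus lining of the gut above 0 (median 0.26). The enteroendocrine list (16 of 18 above 0, median 0.20) and the enterocyte and copper-cell list (7 of 9, median 0.18) rose as well, with 0 called genes in either. The enterocyte call was lost in 4 of the 6 fits that leave out 1 library and with no batch term (adjusted p from 0.0868 to 0.515).

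The genes nearest to a call at 10% oxygen were higher in all 3 libraries than in the 20% library or libraries of their batch. CG31077 (chromosome 3R, 26999752 to 27002961) stood at 119 and 121 CPM in batch 1 against 43.9 and 35.0 at 20%, and at 7.77 against 2.57 in batch 2, a log2 fold change of 1.60 (SE 0.11, edgeR adjusted p = 0.114). The gene ple, which encodes tyrosine hydroxylase, the first enzyme of dopamine and cuticle-pigment synthesis (3L, 6713356 to 6719525), had a log2 fold change of 1.24 (SE 0.09), and to (takeout), a secreted carrier-like protein linked to feeding (3R, 25240180 to 25241668), one of 1.20 (SE 0.09), both with adjusted p = 0.114. Insertions of the retrotransposon copia on 2L (17819978 to 17825122) and 3R (4105093 to 4110238) had log2 fold changes of 0.94 and 1.13. Reads of near-identical copies can be split between insertions. On the lower side the smallest p-values belonged to CG17159, CG7950 (-1.89), CG7458 (-0.39), CG9396 (-0.50) and Gabat, the GABA-degrading transaminase (-0.88, SE 0.17), with adjusted p from 0.148 to 0.509. CG7950 overlaps another gene on the same strand, and its level summed with that gene was not examined. CG17159 was at 0 in all 3 libraries at 10% and at 60 to 77 counts at 20%, at least 20-fold above the floor of 3 counts in each, but it overlaps CG17162 on the same strand, and the sum of both was 14.9, 15.1 and 19.7 CPM at 10% against 13.9, 14.1 and 14.2 at 20%.

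Genes of the classical low-oxygen response showed no call at 10%. The hypoxia response list had a median of 0.01 over 11 tested genes, and the sign turned with length offsets, on the TPM scale and with the length trend removed. Its transcription factor sima, the fly HIF-1 alpha, had a log2 fold change of 0.01 (SE 0.07), the oxygen-sensing prolyl hydroxylase Hph -0.02 (SE 0.08), and lactate dehydrogenase, Ldh, 0.35 (SE 0.19, adjusted p = 0.802). Hph overlaps another gene on the same strand. Glycolysis genes had a median of -0.04. The progenitor list had a median of -0.00 over 13 genes: esg, the transcription factor of gut stem and progenitor cells, differed by -0.00 (SE 0.16) and Delta, the stem-cell Notch ligand, by -0.16 (SE 0.26). The sign of the progenitor median turned with DESeq2 size factors and on the TPM scale. The cytokine gene upd3 (-0.16, SE 0.24) and the detoxification gene GstD1 (-0.07, SE 0.09) did not pass either.

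Another 24 lists did not pass at 10% oxygen. Their medians were -0.04 for mitochondrially encoded genes, -0.04 for antioxidant enzymes, -0.07 for glutathione S-transferases, 0.05 for P450s, 0.06 for UDP-glycosyltransferases and 0.27 for metallothioneins. They were 0.02 for endoplasmic reticulum stress, 0.24 for antimicrobial peptides, -0.02 for the Imd pathway, 0.02 for JAK-STAT, 0.08 for JNK signalling, 0.09 for EGFR, 0.03 for insulin and FOXO and 0.01 for DNA damage repair. Ribosomal proteins (-0.02), proteasome (0.04), lipid synthesis (0.06), lipid breakdown (-0.05), serine proteases (-0.02), proton pumps (-0.08) and septate junctions (0.07) lay near 0, with neurons at 0.13, trachea at -0.00 and haemocytes at -0.33. On the TPM scale the Imd, trachea and haemocyte medians lay above 0, and with the length trend removed the sign of the JAK-STAT, insulin, DNA repair, ribosomal and protease medians turned.

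Marker lists of other tissues moved at 10% oxygen too. The ovary list fell (median -1.26, 12 of 15 genes below 0), as did the Malpighian tubule and hindgut list (-0.41, 10 of 11) and the muscle list (-0.18, 15 of 16), and the fat body list rose (0.75, 4 of 5). None of these calls held by camera with an estimated correlation (adjusted p = 0.622, 0.718, 0.718 and 0.446). Without replicate 2 at 10%, the ovary list was at -0.45 (adjusted p = 0.438) and the tubule list at -0.05 (adjusted p = 0.656), neither passing. Without replicate 1 at 10% they were at -3.62 and -1.15, and without replicate 1 at 20% the ovary list was at -0.32. The fat body list was at 0.37 without replicate 1 and 1.14 without replicate 2 at 10%, and the TCA cycle list at -0.09 without replicate 2 at 10%. Without replicate 2 at 10% the cell cycle list stood at -0.61 and passed. Without replicate 2 at 20% the cell cycle list stood at -0.29 and passed. The heat shock list also fell (-0.14, 10 of 15), but it did not pass in batch 1 alone (median -0.01, adjusted p = 0.868). It was also lost without replicate 3 at 10% (-0.04) or at 20% (-0.01), and stood at -0.29 and -0.23 without replicates 1 and 2 at 10% and at -0.23 without replicate 1 at 20%. The tubule list was lost without replicate 3 at 10% (-0.43) or any replicate at 20% (-0.55, -0.30 and -0.43), and the muscle list without replicate 1 at 10% (-0.11) or 20% (-0.08), with a median of 0.12 and no call with no batch term. The muscle median was -0.38 without replicate 3 at 10% or at 20% and -0.37 in batch 1 alone. The enterocyte list was lost without replicate 1 (0.18) or 2 (0.11) at 10% and 1 (0.19) or 2 (0.10) at 20%, or with no batch term (0.21). The enteroendocrine list was lost without replicate 2 at 20% (0.13), and the peritrophic matrix list with no batch term (0.28). Mean levels of the cell cycle list were 1.49, 1.38 and 0.99 log2 CPM in replicates 1, 2 and 3 at 10% and 1.65, 2.34 and 1.27 at 20%.

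Of the 124 genes that DESeq2 called among the 9278 tested, 98 were higher and 26 lower. Over the list alone the fixed lists gave calls for Cyp4aa1, MtnD, ACC, dve, to, Muc68D, Cht8 and Cht5, all higher. The count adjusted over the list alone was 3 for the peritrophic matrix list, 1 each for the P450, metallothionein, lipid synthesis, enterocyte and fat body lists and 0 for all others. By camera at the preset correlation, adjusted p ranged from 1.19e-17 for oxidative phosphorylation to 0.04 for heat shock and tubule. With an estimated correlation adjusted p = 0.446 for the TCA cycle, oxidative phosphorylation, carbohydrate, peritrophic matrix, enteroendocrine, enterocyte and fat body lists, 0.502 for heat shock, 0.620 for cell cycle, 0.622 for ovary, and 0.718 for muscle and tubule.

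**Figure D2:**
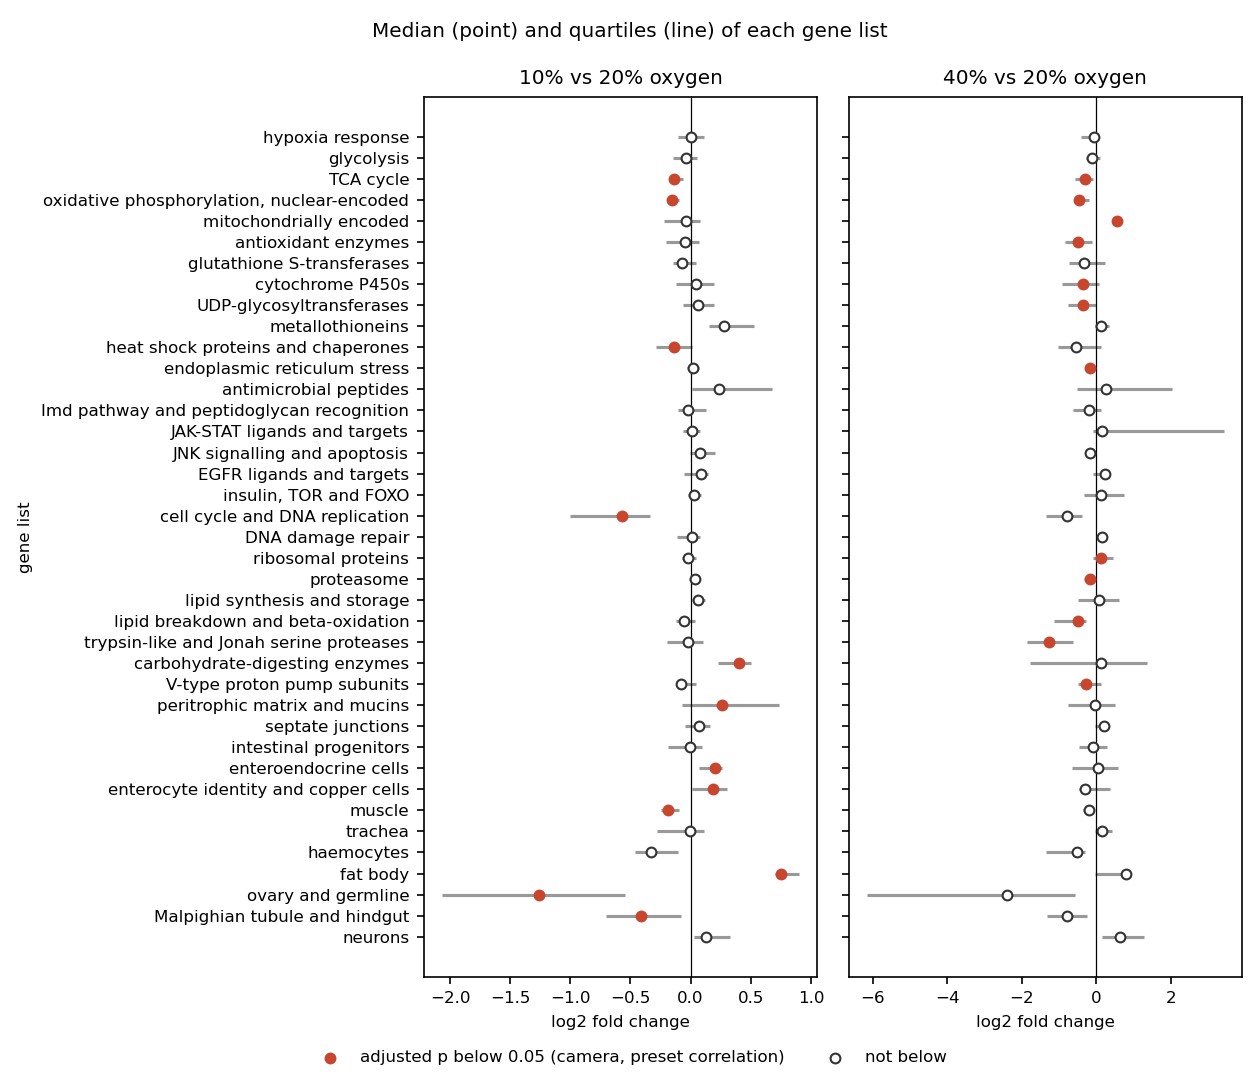
Median log2 fold change (point) and quartiles (line) of the tested members of each of the 39 gene lists for 10% against 20% oxygen (left) and 40% against 20% oxygen (right, on a wider axis), with filled points for lists with an adjusted p below 0.05 by camera at the preset correlation. The nuclear-encoded oxidative phosphorylation list lies below 0 in both panels (-0.15 and -0.45), the mitochondrially encoded list lies at 0.56 in the right panel, and the serine proteases lie at -1.28 in the right panel only.

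The 40% library had far fewer transcripts of secreted digestive proteases than any other library. The trypsin-like and Jonah serine proteases, the main protein-digesting enzymes of the fly midgut, took 1.85% of its counts against 5.39% and 5.13% in the other libraries of batch 2, or 6.38% against 13.8% and 14.2% of counts outside the mitochondrial genome. Against 20% oxygen 28 of the 30 tested proteases had fold changes below 0, with a median of -1.28, and 8 fell by the test over all genes. Jon25Bi (2L, 4954279 to 4955144) stood at 570 CPM against 3950 in the 20% library of batch 2, a log2 fold change of -2.85 (SE 0.28, edgeR adjusted p = 0.0331). Its neighbour Jon25Bii (2L, 4952243 to 4953136) fell by 2.94 on the log2 scale and Jon99Fi (3R, 30488963 to 30489895) by 3.16. Jonah genes are close paralogs between which reads can be split.

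In all, 319 of 10068 genes differed at 40% oxygen, 142 higher and 177 lower. Among the genes that rose most were ple, at 65.7 CPM against 4.46 in the 20% library of batch 2 (log2 fold change 3.85, SE 0.14, adjusted p = 0.00501), and sNPF, the short neuropeptide F precursor (2L, 20027915 to 20056373), at 38.6 CPM against 1.97 to 3.25 in the 20% libraries (3.95, SE 0.36, adjusted p = 0.0331). CG11029 (3.90), to (3.05, the 1 called gene of the fat body list), the tetraspanin gene Tsp66E (2.61) and GNBP-like3 (2.62) rose too. The antimicrobial peptide gene Def rose to 542 CPM against 79.8 (2.69, SE 0.32). Of the other 13 tested antimicrobial peptide genes none passed over all genes, and the list, with a median of 0.26 that was -0.03 with the length trend removed, did not pass. MtnA, a metal-binding metallothionein, rose to 27300 CPM against 5900 (1.99, SE 0.23) as the 1 called member of 5. Its levels in batch 1 were 588 to 800 CPM. With the length trend removed Def stood at 2.25 and MtnA at 1.37, neither called. Besides the proteases, the named genes that fell most were Npc2d, an NPC2 family gene (34.5 against 257 CPM; -2.94, SE 0.12, adjusted p = 0.00527), shd, the enzyme that makes active ecdysone (-3.23, SE 0.45), the cytochrome P450 gene Cyp4d1 (-2.86, SE 0.25) and CG13813 (-2.92, SE 0.44). HemK2 and CG42306 were called at 11.63 and -12.22, but both are all-or-none genes that overlap another gene on the same strand: HemK2 was at 0 in batch 2 at 10% and 20%, where its partner Snapin stood at 15.7 and 15 CPM, and the sum of the pair was 15.8 CPM at 40% against 15 at 20%. CG42306 was at 0 at 40%, where its partner Gint3 stood at 27.3 CPM, and the sum of that pair was 27.3 CPM against 40.9 in batch 2 at 20%.

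Digestive enzymes other than proteases split. All 5 called members of the carbohydrate-digesting list were alpha-mannosidases of the LMan family and fell: LManV (2L, 8772946 to 8776263) stood at 112 CPM against 545 in batch 2 at 20% (-2.52, SE 0.33), with LManII at -2.12 and LManI at -2.03. Adjusted over the list alone 8 members were lower, adding LManVI, Amy-p and Amy-d, and 6 higher, the maltase genes Mal-A8, Mal-A6, Mal-A7 and Mal-B2 with tobi and Amyrel. The list did not pass; its median was 0.13 and its mean -0.09. LMan genes are paralogs between which reads can be split. In the peritrophic matrix list Muc68D, a gut mucin (2.17, SE 0.20), and the chitinase gene Cht8 (2.31, SE 0.24) rose, Cht9 fell (-1.83, SE 0.27) and 21 of 24 members did not pass, nor did the list (median -0.05, and -0.30 with the length trend removed). Muc68D and Cht8 lay lower in batch 2 as a whole, at 136 and 9.62 CPM at 40% against 28.2 and 1.97 at 20%, with 269 to 348 and 21.0 to 28.7 CPM in batch 1 at 20%.

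The nuclear-encoded oxidative phosphorylation and TCA cycle lists fell and the mitochondrially encoded list rose. None of these 3 calls held with an estimated correlation (adjusted p = 0.509, 0.356 and 0.564), and the lists were not tested against each other. Of the 70 tested nuclear-encoded subunits of oxidative phosphorylation 12 fell and 1 rose, with a median of -0.45. ND-24 of complex I (-0.96, SE 0.11) and COX7A of complex IV (-0.81, SE 0.11) fell, and ND-AGGG rose (1.16, SE 0.14). With the length trend removed they stood at -0.91, -0.93 and 0.81, none called. Adjusted over the list alone 41 were lower and 5 higher. Citrate synthase, kdn, was the 1 called gene of the TCA cycle (-0.62, SE 0.10), which had a median of -0.30 and 9 genes lower adjusted over the list alone. The 12 tested protein-coding genes of the mitochondrial genome all had fold changes above 0, with a median of 0.56. It was 1.08 without replicate 3 at 20%, 1.91 with no batch term and 0.40 relative to all genes on the TPM scale. Of these genes none passed over all genes and 4 were higher adjusted over the list alone, in the library where mitochondrial transcripts took 71.0% of counts.

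The antioxidant, P450 and UDP-glycosyltransferase lists fell, and none of the 3 calls held with an estimated correlation (adjusted p = 0.356, 0.509 and 0.564). In the antioxidant list (median -0.49) 4 of 23 fell and none rose: Fer1HCH, the iron-storing ferritin heavy chain, stood at 895 CPM against 1760 in batch 2 at 20% (-1.06, SE 0.14, adjusted p = 0.0392), Keap1, the inhibitor of the oxidative stress factor cnc, at -0.97 (SE 0.12), the peroxiredoxin Prx6c at -2.25 (SE 0.31), and Trxr1 was the other called member. Adjusted over the list alone 8 were lower, among them Sod2 and Cat. Of 76 tested cytochrome P450s (median -0.35) 5 fell, among them Cyp6t1 (-2.06, SE 0.23) and Cyp12a4 (-0.99, SE 0.11), and 1, Cyp4aa1, rose. Cyp12a4 overlaps another gene on the same strand. Of 32 UDP-glycosyltransferases (median -0.36) 4 fell, with Ugt37A1 at -2.17, Ugt37B1 at -1.89 and Ugt37A3 at -1.0. Of 31 glutathione S-transferases GstE8 (1.0, SE 0.16) and GstE9 (0.85, SE 0.13) rose, none fell over all genes, and the list, with a median of -0.33, did not pass. GstD1 was at -0.19 (SE 0.15), not called.

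The called genes of each lipid list were lower. The peroxisomal acyl-CoA oxidases Acox57D-d (-1.46, SE 0.14) and Acox57D-p (-1.61, SE 0.22) fell, 11 of 12 genes of lipid breakdown had fold changes below 0 (median -0.49) and 7 were lower adjusted over the list alone. In lipid synthesis and storage, which did not pass as a list (median 0.06, and -0.07 with the length trend removed), the lipid-droplet genes Lsd-2 (-1.28, SE 0.18) and Seipin (-1.43, SE 0.18) fell, and adjusted over the list alone FASN1, ACC, Desat1 and mdy were higher. In the insulin and FOXO list foxo, the transcription factor that insulin signalling restrains, rose to 74.7 CPM against 29.2 to 38.8 at 20% (1.02, SE 0.12, adjusted p = 0.0363), and adjusted over the list alone InR, ImpL2 and step were higher and Sesn lower. That list did not pass, with a median of 0.12, and -0.00 relative to all genes on the TPM scale. With the length trend removed foxo stood at 0.91, not called. Among 85 ribosomal protein genes 5 rose and none fell, among them RpL41 (1.85), RpL39 (1.36) and RpS18 (0.65); the list median was 0.11, and on the TPM scale, relative to the median of all genes, it was -0.05. With the length trend removed RpL41 stood at 1.18 and RpL39 at 0.57, neither called.

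Among cell types, 1 of 18 enteroendocrine genes rose, the peptide hormone gene CCHa2 (265 against 112 CPM in batch 2; 1.16, SE 0.16), and 1 fell, Orcokinin (-1.09, SE 0.15); the list, at 0.05 and at -0.15 relative to all genes on the TPM scale, did not pass. Vha100-4, a proton pump subunit of copper cells, the acid-secreting cells of the midgut, fell (-1.32, SE 0.20) as the 1 called gene of both the enterocyte list (9 tested, median -0.31) and the proton pump list (23 tested, median -0.28). Relative to all genes on the TPM scale these medians were -0.11 and -0.44. The caspase gene Dcp-1 fell (-1.10, SE 0.13), the 1 called gene of JNK signalling and apoptosis, whose median was -0.16 with no list call. The metallothionein list (0.11, but -0.51 with the length trend removed and -0.09 relative to all genes on the TPM scale) did not pass. Nor did the fat body list (0.79, and 0.21 with the length trend removed, 0.36 without the 20 most abundant genes and 1.44 relative to all genes on the TPM scale). No progenitor gene was called; the list's median was -0.08, above 0 with the length trend removed, esg was at -0.00 (SE 0.27), Delta at 0.98 (SE 0.43, adjusted p = 0.287) and upd3 at -0.37 (SE 0.44). The hypoxia response list was at -0.05, and -0.24 with the length trend removed, with sima at -0.05 (SE 0.11), and -0.30 with that trend removed, Hph at -0.38 (SE 0.13) and Ldh at -0.44 (SE 0.31), none called. Lists that did not pass and held no called gene were glycolysis (-0.11), heat shock (-0.55), Imd pathway (-0.20), JAK-STAT (0.16), EGFR (0.23), cell cycle (-0.79), DNA damage repair (0.15), septate junctions (0.20), muscle (-0.19), trachea (0.14), haemocytes (-0.53), ovary (-2.40), Malpighian tubule and hindgut (-0.79) and neurons (0.62). With the length trend removed the medians were -0.06 for septate junctions, 0.05 for JAK-STAT and EGFR, -0.30 for muscle, -0.83 for haemocytes and 0.33 for neurons. On the TPM scale, relative to all genes, they were -0.13 for cell cycle, -0.54 for ovary, -0.19 for heat shock, 0.05 for EGFR, 0.01 for trachea and -0.35 for haemocytes.

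**Figure D3:**
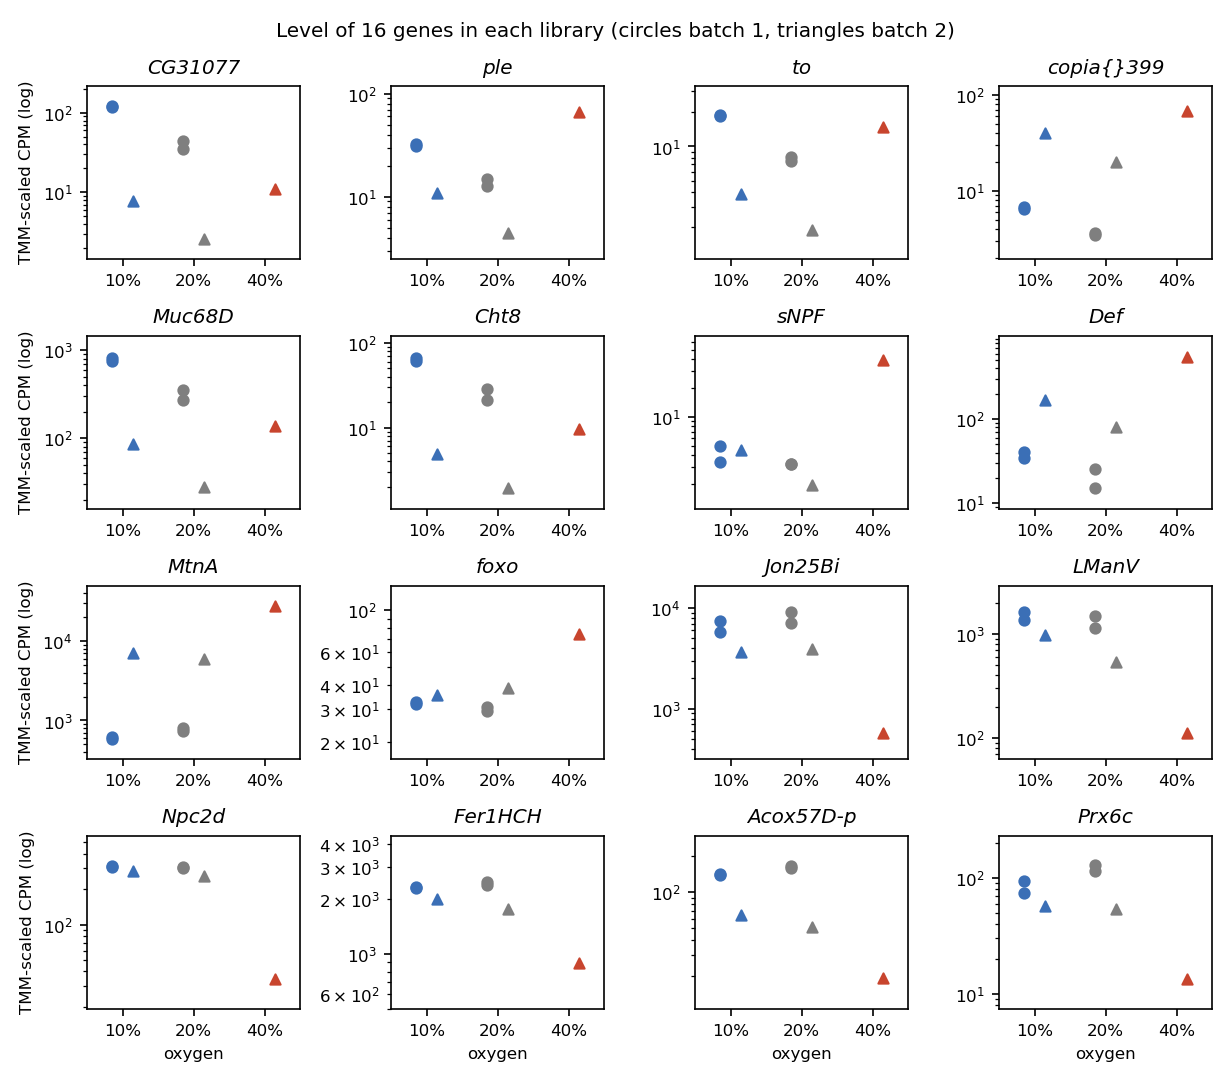
TMM-scaled CPM (log axis) of 16 genes in each library by oxygen level, with circles for batch 1 and triangles for batch 2. Within batch 2 the 40% library lies above the 20% library for the first 10 genes (ple at 65.7 against 4.46) and below it for the last 6 (Jon25Bi at 570 against 3950).

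By camera at the preset correlation 12 lists passed, and none of them with an estimated correlation (adjusted p from 0.356 to 0.754). The mitochondrially encoded and ribosomal lists were higher, and the protease, oxidative phosphorylation, TCA cycle, antioxidant, lipid breakdown, P450, UDP-glycosyltransferase, proton pump, proteasome (median -0.17) and endoplasmic reticulum stress (median -0.18) lists lower. By fry the TCA cycle (adjusted p = 0.0178), antioxidant (0.033) and lipid breakdown (0.0448) lists passed, and the others of the 12 did not (0.0636 to 0.27). Adjusted p by camera ranged from 7.45e-16 for the proteases to 0.047 for endoplasmic reticulum stress. That list was lost with DESeq2 size factors (-0.14), with no batch term (-0.63), and without any 1 of replicates 1 (-0.16) or 2 (-0.18) at 10% and 1 (-0.18), 2 (-0.17) or 3 (-0.08) at 20%. Without replicate 3 at 20% the UDP-glycosyltransferase (-0.43) and proteasome (-0.14) lists were lost too, and with no batch term the proteasome (-0.25) and proton pump (-0.65) lists. Lists that passed but moved by over 1.5 times were P450s (-0.21 without replicate 3 at 10%, -0.22 without replicate 1 at 20%), UDP-glycosyltransferases (-0.22 without replicate 3 at 10%), and, without replicate 3 at 20%, ribosomal proteins (0.04) and mitochondrially encoded genes (1.08). With no batch term these were TCA cycle (-0.67), antioxidant enzymes (-0.79), lipid breakdown (-0.83), UDP-glycosyltransferases (-0.79), oxidative phosphorylation (-0.27), ribosomal proteins (0.65) and mitochondrially encoded genes (1.91). With an estimated correlation adjusted p = 0.356 for TCA cycle and antioxidant enzymes, 0.509 for proteases, oxidative phosphorylation, P450s and lipid breakdown, 0.564 for mitochondrially encoded genes and UDP-glycosyltransferases, 0.604 for endoplasmic reticulum stress, 0.687 for proton pumps, 0.740 for proteasome and 0.754 for ribosomal proteins. Adjusted over the list alone, 20 proteases, 6 UDP-glycosyltransferases, 12 P450s and 7 proton pump genes were lower and 13 ribosomal protein genes higher. Over all 10068 genes 2115 had an unadjusted edgeR p below 0.05, and the counts over a list alone were not set against random lists of genes.

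The 40% group is 1 library of batch 2, so its difference from 20% has no replicate check and cannot be told apart from a property of that library; all 319 calls lay beyond both other libraries of batch 2. The count fell to 0, 2 and 69 without replicates 1, 2 and 3 at 10% oxygen, to 1, 1 and 15 without those at 20%, to 1 with no batch term and to 100 with the length trend removed. DESeq2 called 972, and on the TPM scale, where the median gene moved by -0.32, it was 85 higher and 1341 lower.

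Against 10% oxygen the 40% library differed in 117 genes, 45 higher and 72 lower, of which 115 were also called against 20%, all in the same direction. Both comparisons share the 40% library and the same fit, so this overlap is no independent check. The genes with the largest differences were again sNPF (3.34, SE 0.35, adjusted p = 0.0432) and ple (2.61, SE 0.13, adjusted p = 0.0127) on the higher side and Npc2d (-3.01, SE 0.12, adjusted p = 0.007) and LManV (-2.92, SE 0.33) on the lower, beside the all-or-none genes HemK2 (11.55) and CG42306 (-12.17). Scaling by DESeq2 size factors left 4 calls, 2 in each direction, and removing the length trend also left 4, 2 in each direction. No batch term left 1, the TPM scale (median shift -0.32) gave 45 higher and 1362 lower, and DESeq2 called 815. Leaving out replicates 1, 2 and 3 gave 0, 1 and 1 calls for those at 10% and 0, 0 and 56 for those at 20%.

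No gene was called by edgeR in both 10% and 40% against 20%, since none was called at 10%. DESeq2 called 82 genes in both, 80 of them in the same direction. Of these 66 were higher and 14 lower, against 4.64 and 1.47 for independent lists of those sizes, and 10 simulations of unchanged groups that shared the 20% libraries gave 1 to 7 genes called in both. In those simulations every call was false. DESeq2 called 11 to 33 genes at 10% and 8 to 30 at 40% in them, against 124 and 972 in the data. An overlap of 82 could not arise in them, so they are no measure of it for lists of the real sizes. Log2 differences were taken over 6618 genes for 10% against 20%, weighted over the batches, and for 40% against 20% in batch 2. Their covariance was 0.0718, against a mean of 0.0377 in 50 simulations of unchanged groups. Their correlation was 0.355, against a mean of 0.293 and a range of 0.232 to 0.352 simulated. Between 10% against 20% in batch 1 and 40% against 20% in batch 2, which share no library, the correlation was 0.192, against -0.0875 to 0.0615 simulated. Genes are not independent replicates, and with 3 control libraries the count of genes called in both could not be repeated with separate sets of at least 2 controls, so part of its excess may come from the shared controls.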

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

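Removal of the length trend, removal of all-or-none genes and list tests in batch 1 alone were chosen after seeing the data. For 10% against 20% oxygen edgeR called 0 genes in every edgeR setting run, with 584 at an unadjusted p below 0.05, while DESeq2 called 124 and limma voom 1; the cause was not tested. A replicate block left 0 called genes and the same 12 lists. With an estimated correlation 0 lists passed for 10% and 0 for 40%, and the cause was not tested. By fry the TCA cycle and fat body lists passed for 10%, and the TCA cycle, antioxidant and lipid breakdown lists for 40%. DESeq2 called 82 genes in both comparisons. For 40% against 20% the count of 319 became 972 with DESeq2, 1 with no batch term, 1426 on the TPM scale, where the median gene moved by -0.32, and 0 to 69 leaving out replicates. For 40% against 10% the count of 117 became 4 with DESeq2 size factors, 815 with DESeq2, 193 with no low-count filter, 1 with no batch term, 1407 on the TPM scale and 0 to 56 leaving out replicates. Removal of the length trend gave 100 and 4 calls, and leaving out all-or-none genes gave 221 for 40% against 10%. With no batch term Cht8 was at -0.846 and Muc68D at -0.662, the reverse of the values with it, since both lie lower in batch 2. Of the 49 named genes called at 40%, 27 lost their call with the length trend removed, though all 319 called genes kept their sign. Folds such as those of Prx6c (-2.25 to -2.21) and Acox57D-p (-1.61 to -1.58) moved little. RpL39 went from 1.36 to 0.57 and MtnA from 1.99 to 1.37. Leaving out replicates lowers the number of samples; the cause of the other changes was not tested. At 3 counts the floor was 0.135 to 0.156 CPM before TMM scaling, so genes below 3 counts could not be compared. The 40% library had 5.73 M counts outside the mitochondrial genome.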

Other observations

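The calls of genes in each comparison, the count called in both and the camera tests of lists at both correlations were planned. The other tests in this part were chosen after the first results were seen. For the length trend, the library set apart, the germline covariate and the comparison sharing no library, the bounds were written before the value was computed. Of the genes that DESeq2 called in both comparisons, none of which edgeR called at 10%, those named here were chosen by hand after their values were seen, and no group of them was tested. At 10%, DESeq2 called 11 to 33 genes in 10 simulations of unchanged groups, all of them false, against 124 in the data. Higher in both, at 10% and at 40%, were ple (1.24 and 3.88), Muc68D (1.43 and 2.2), the chitinase gene Cht8 (1.35 and 2.35), Pgant4, which attaches sugars to mucins (1.56 and 1.83), and the lipid transporter gene snu (0.56 and 0.71). The fatty acid genes ACC (0.37 and 0.63), Baldspot (0.34 and 1.25), CG31522 (0.35 and 1.39) and Fatp2 (1.65 and 3.25) and the antimicrobial peptide genes Def (0.96 and 2.73) and DptA (1.1 and 2.4) were higher too. Lower in both were the ATP synthase genes blw (-0.17 and -0.57), ATPsynB (-0.22 and -0.63) and ATPsyngamma (-0.21 and -0.52), citrate synthase kdn (-0.17 and -0.59), the ATP carrier sesB (-0.25 and -0.34), the channel porin (-0.20 and -0.30) and Cyt-c-p (-0.37 and -0.67).

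Of the 82 genes 19 were transposon features. Summed by family, 74 transposon families were tested in both comparisons with edgeR: 0 were called at 10%, and over the families alone 6 rose and 1 fell at 40%. The families that rose were copia (1.09), roo (1.76), springer (2.85), Transpac (2.58), blood (1.03) and opus (1.91), and accord fell (-1.74). At 10% copia was at 0.52 (SE 0.087, edgeR adjusted p = 0.125 over families), and all 32 tested copia features had fold changes above 0 in both comparisons; 11 were called at 40%. All-or-none genes overlapped another gene on the same strand in 134 of 269 cases (49.8%), against 684 of 8144 other tested genes with at least 50 counts in a library (8.4%).

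Serine protease genes were lower in the 40% library. Removal of a per-library length trend, a test of short-fragment bias, moved other genes and lowered the calls from 319 to 100, but left the protease median at -1.26 (quartiles -1.81 and -0.57) against -1.28 (-1.85 and -0.63), which argues against length bias as the whole cause. Of 8 called proteases 6 were called after it; Jon25Bi, at -2.82 against -2.85, stayed called at an edgeR adjusted p of 0.0441 against 0.0331. A further shift along the batch difference would raise muscle genes, 4.14 higher in batch 2, and tracheal genes, 2.77 higher. Their medians at 40% were -0.193 (upper quartile -0.08) and 0.14 (upper quartile 0.415). Mitochondrially encoded genes, 5.07 higher in batch 2, did rise at 40% (median 0.56). Single called genes went both ways: RpL41 was higher in batch 2 and rose at 40%, while Muc68D was lower in batch 2 and rose. The 40% library also had the highest mitochondrial share, the shortest fragments and the outermost place on the first principal component (96.9 against 73.5 and 69.7). A shift of this kind in part of the genes therefore stays open. With 1 library, an effect of oxygen cannot be told apart from a property of that library. Each of the other 6 libraries was set apart alone, in fits without the 40% library. The highest count was 44, for replicate 2 at 10%. The 319 calls for the 40% library are those of its main test, a different fit, so they cannot be ranked against these counts. With 7 libraries a share under 0.05 could not arise in any case.

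The cell cycle and ovary lists were lower at 10% oxygen by camera at the preset correlation, with 0 called genes in either and neither call held with an estimated correlation (adjusted p = 0.620 and 0.622). With the germline level of each library as a covariate, the cell cycle median was -0.402 (quartiles -0.68 and -0.20) against -0.57. This met the bound written beforehand against ovary RNA as the cause, but that bound was set on genes; across the 6 libraries the difference was -0.36 (SE 0.37) with the covariate and -0.59 (SE 0.29) without it, so the ruling was changed after the values were seen and ovary RNA stays open. For the calls at 10% the real count was 0, so all 10 splits of the 6 libraries into 3 and 3 had to give at least as many. The splits therefore decide nothing, and 10 are too few for a share under 0.05. The highest other count was 44, for the split that, within batch, sets replicate 2 at 10% apart. That split follows a structure of the samples, the 1 library that stood apart in Uro and osk.

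Fold changes at 10% and at 40% shared a direction in part: in comparisons that share no library, 54.7% of 6618 genes had the same sign, against 50% in simulations of unchanged groups. Between 10% against 20% in batch 1 and 40% against 20% in batch 2, which share no library, fold changes correlated at 0.192, against -0.0875 to 0.0615 in 50 simulations of unchanged groups. Shared controls cannot act there, so they are not the cause of this correlation. Genes were simulated as independent, so the simulated range may be too narrow. Replicate 2 at 10%, which stood apart in Uro and osk, is also part of the correlation. Whether it exceeds that of unchanged groups therefore stays open. Ovary and tubule RNA, which differed between libraries, could add to the correlation: with replicate 1 of 10% against replicate 1 of 20%, whose germline levels were close, the correlation was 0.091 against -0.0841 to 0.074 simulated. That lies above every simulated value, as the bound set for it asked, but by less than 1 simulated SD (0.038), a margin required of both correlations only after the values were seen and met by the first, and with 1 library per group and genes simulated as independent it decides nothing. Effects of oxygen that both levels share stay open, as untested.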
